A study of Mus musculus with 91 samples.

How the data were processed

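Total RNA of frontal cortex and whole hippocampus of the left hemisphere was labelled with biotin and hybridised to Illumina bead arrays, 45 of cortex and 46 of hippocampus, per the labels. The deposited signal table holds, for each array, an intensity and a detection p-value of 25697 probes, per the file headers. Many deposited intensities lay below zero, so a background had been subtracted before deposit; how is not given in the sources used here. The submitters' processing notes name BeadStudio, GenomeStudio and Partek, without versions. The detection p-value, of which the file headers give only the name, is a measure of how often background reads as bright as the probe. The submitters' deposited value table holds 17885 of the probes on a log2-like scale, with a median of 7.434 on every cortical and 7.23 on every hippocampal array. Its order of probes within an array was that of the signal table (rank correlation 1), and its columns had been made equal in distribution within each tissue. The offset and background step behind its scale stay unknown. Array annotation gave 16814 probes a single gene symbol (12115 genes), 0 several and 8883 none, and 16806 were matched through their gene number to the current gene table, which changed 0 symbols. Probes without a symbol were tested and counted but not named.

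Groups came from genotype and treatment in the labels. The treatment text counts 8 and 11 PBS mice where the titles hold 9 APP/PS1 and 12 WT, and the titles were used. Animal numbers tie the arrays of both tissues to 47 mice, and replicates are separate mice. Chip and collection day were read from the labels.

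The main values were computed per tissue from the deposited intensity and detection p-value with neqc of limma 3.58.1 (R 4.3.3), a background correction by the normal-exponential model with parameters inferred from detection p-values, an offset of 16, quantile normalization and log2. Probes were kept where the detection p was under 0.05 on at least 9 arrays of the tissue, with Cd33, App and Thy1 kept in any case, leaving 14346 probes in cortex (9958 genes, 815 of the probes unnamed) and 14449 in hippocampus (10042 genes, 808 unnamed). A limma model with 1 mean per group over all 4 groups of a tissue, so that all share 1 estimate of spread, was fitted with empirical Bayes moderation (trend and robust), and the Benjamini-Hochberg adjusted p threshold was 0.05. All p-values are two-sided. The fold of a probe not detected on any array of 1 group is given as "at least", the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest detected signal and the probe's own. Differences between tissues were tested as interactions in a joint normalization of all 91 arrays, with 8 groups and the mouse as a random block (within-mouse correlation 0.169, 14884 probes, statmod 1.5.0).

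Gene lists, 33 in number, were tested with camera at a preset correlation of 0.01, with camera at a correlation estimated for each list, and with fry, using the brightest probe of each gene and Benjamini-Hochberg adjustment over the lists of a comparison. They cover pan-microglia, homeostatic and plaque-associated microglia, CD33 family and its signalling, complement, interferon response, antigen presentation, inflammatory cytokines and NF-kappaB, nucleic acid sensing and Toll-like receptors, lysosome, astrocytes and reactive astrocytes, neurons, interneurons, immediate early genes, oligodendrocytes and myelin, oligodendrocyte precursors, endothelium and pericytes, choroid plexus and ependyma, meninges and fibroblasts, blood cells, perivascular and border macrophages, T, NK and B lymphocytes, striatum and hippocampal fields as dissection markers, p53 targets, unfolded protein response, cholesterol synthesis, lipid efflux and lipoproteins, amyloid precursor processing and clearance, orthologues of Alzheimer's disease risk genes, mitochondrial respiration and cell proliferation. In the text, "estimated" beside a p stands for the estimated correlation.

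The rule for named genes took Cd33 always and App and Thy1 for the genotype, and a further gene that it took is not reported here. From each comparison it took the 12 largest rises and 12 largest falls among genes past the threshold, and up to 4 members of smallest p from each list with an adjusted p under 0.05. For differences between tissues it took the 5 genes of smallest p. Not every gene the rule names is printed. Groups, models, lists, this rule and the first set of alternatives were fixed before the data were examined. That set held no background correction, median centring in place of quantile normalization, joint normalization of both tissues, the submitters' value table, no filter and a stricter filter (detection p under 0.01 in at least 0.5 of the arrays), array weights, chip or day as a block, the replicate number as a block, the compared groups alone, 1 probe per gene, each array left out in turn, and no mouse block for the interaction. The fit with the replicate number as a block kept only arrays numbered up to 9, the size of the smallest group. Chosen after seeing the data were fits without arrays of weight under 0.5, with the striatum or choroid plexus list mean as a covariate, without CD33 ASO replicate 3, with mice of both tissues alone, and with both of these exclusions.

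Correlations were tested with 100000 permutations. Other splits of the samples were drawn 100 times with seed 1. The fits were tested on simulated data with 200 changed probes in 20 runs. At a change of 0.5 on the log2 scale they recovered 86.1% of changed probes for CD33 ASO against CON ASO in cortex and 84.8% in hippocampus, and at 0.25, 43.6% and 38.6%, with 6.97% and 4.96% of calls false. At 0.5 they recovered 81.3% and 76.5% for genotype, 84.2% and 78.4% for CON ASO against PBS, and 81.3% and 77.5% for CD33 ASO against PBS. In the simulated lists of CD33 ASO against CON ASO, camera at the preset correlation called 5.8 of 32 unshifted lists in cortex and 6.2 in hippocampus, and 0.1 and 0 with an estimated correlation, so a shift at the preset correlation alone is a weak call. For the interaction of genotype and tissue 71% of changed probes were recovered at 0.5 and 98% at 1.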

Results

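Gene expression was measured with Illumina bead arrays, glass chips on which each transcript is read by a probe carried on many beads, in the brains of APP/PS1 mice (APPPS1 in the sample titles) and their wild-type (WT) littermates. APP/PS1 mice are a double transgenic model of Alzheimer's disease and deposit amyloid plaques. The series asked what lowering CD33, a sialic acid-binding inhibitory receptor of microglia and other myeloid cells whose human gene carries Alzheimer's disease risk variants, does to gene expression in this model. APP/PS1 mice received an antisense oligonucleotide (ASO, a short synthetic strand that pairs with a messenger RNA and lowers it) against CD33, a control oligonucleotide without a target (CON ASO), or phosphate-buffered saline (PBS), and WT littermates received PBS. Osmotic pumps delivered 50 µg of oligonucleotide per day into the right lateral ventricle for 14 days from 18 weeks of age, and tissue of the left hemisphere was taken at 22 weeks.

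The 91 arrays came from 47 mice, 44 of them with an array of both tissues. Frontal cortex was measured in 12 WT PBS, 9 APP/PS1 PBS, 13 CON ASO and 11 CD33 ASO mice, and hippocampus in 12, 9, 13 and 12. Each array detected between 12555 and 13905 of 25697 probes, and the number of arrays limits the precision. The 3 mice measured in a single tissue were all labelled CD33 ASO. Each tissue lay on 6 chips and 4 collection days, and every chip and day held all 4 groups.

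Cd33 itself was lower in both tissues of the mice labelled CD33 ASO. In frontal cortex the mean log2 signal was 7.08 ± 0.26 (SD, n = 13) under CON ASO and 6.37 ± 0.56 (n = 11) under CD33 ASO. The change was -0.71 ± 0.14 (SE, adjusted p = 0.0147), so that Cd33 fell by 39.1%. The cortical call was lost without background correction (adjusted p = 0.0507) and with the compared groups alone (adjusted p = 0.14). In hippocampus it was 6.52 ± 0.18 (n = 13) and 5.60 ± 0.39 (n = 12). The change was -0.92 ± 0.11 (adjusted p = 1.94e-07), so that Cd33 fell by 47.2%. Both percentages are of signals that hold the added offset of 16, and the size of the fall depends on the processing. Without background correction the log2 change was -0.94 in cortex and -1.30 in hippocampus, and with the submitters' value table -0.60 and -0.75. The probe was detected on 10 of 11 cortical and 8 of 12 hippocampal CD33 ASO arrays and on all arrays of the other groups. The hippocampal change is measured partly at background. APP/PS1 PBS mice stood at 7.10 ± 0.24 in cortex and 6.49 ± 0.23 in hippocampus (n = 9 each), and WT mice at 6.14 ± 0.30 and 5.98 ± 0.20 (n = 12 each). The control oligonucleotide left Cd33 within the spread of PBS (-0.02, adjusted p = 0.973 in cortex, and 0.03, adjusted p = 0.943 in hippocampus). Cd33 was lower under CD33 ASO than CON ASO on 6 of 6 chips in each tissue (-1.32 to -0.23 in cortex, -1.21 to -0.72 in hippocampus) and on 4 of 4 days (-0.91 to -0.42 and -1.09 to -0.71, day 4 with 1 hippocampal CD33 ASO array). With chip as a block the change was -0.73 ± 0.13 in cortex and -0.92 ± 0.10 in hippocampus, and with day as a block -0.67 ± 0.14 and -0.92 ± 0.11.

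Array by array, the target did not separate all labels. The cortical signals of CD33 ASO replicates 1 to 11 were 6.15, 6.36, 5.05, 6.66, 6.34, 6.69, 5.77, 6.48, 6.56, 6.88 and 7.10, and those of replicates 4, 6, 10 and 11 lay within the CON ASO range of 6.62 to 7.55. The hippocampal signals of replicates 1 to 12 were 5.74, 5.51, 5.32, 5.27, 5.69, 5.52, 6.39, 5.50, 5.07, 6.21, 5.75 and 5.27, against a CON ASO range of 6.33 to 6.89. Avil, which encodes the actin-binding protein advillin, separated them further. It was detected on 11 of 11 cortical arrays labelled CD33 ASO and on no CON ASO array, a difference of 1.60 ± 0.12 or at least 1.93-fold (adjusted p = 3.03e-13). In hippocampus it was detected on 10 of 12 against 0 of 13, a difference of 1.50 ± 0.19 or at least 2.05-fold (adjusted p = 2.27e-06). Higher Avil was seen on 6 of 6 chips and 4 of 4 days in each tissue (by chip 1.10 to 2.15 and 0.96 to 2.05). The hippocampal arrays labelled CD33 ASO replicates 7 and 10, whose mice have no cortical array, had Avil at 4.54 and 4.83, not detected, and the highest Cd33 of their group. The labels do not show whether the oligonucleotide reached these mice, and the hippocampal values for CD33 ASO include them.

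**Figure D1:**
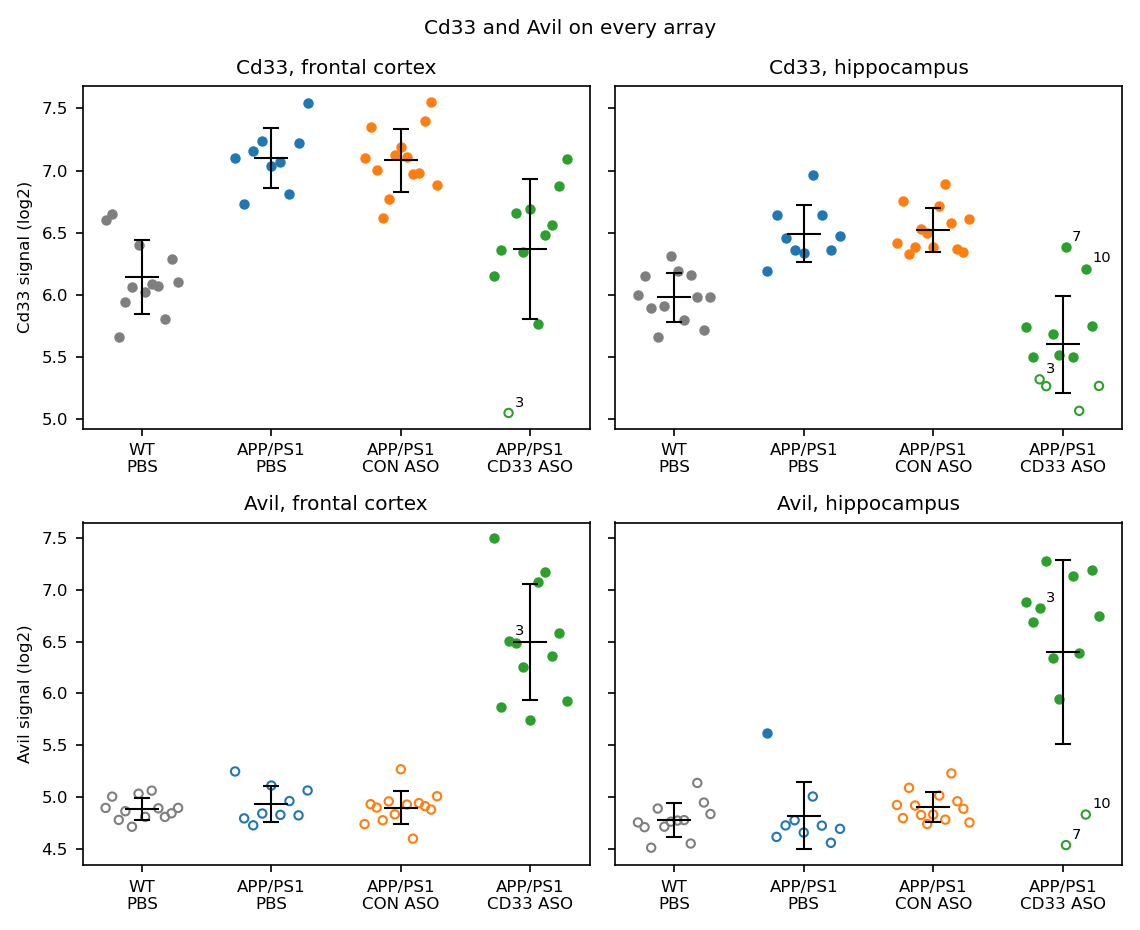
Log2 signal of Cd33 and Avil on each array, by group and tissue; filled points were detected, open points were not, and bars are means with SD. Avil was detected on 11 of 11 cortical and 10 of 12 hippocampal CD33 ASO arrays, and numbers mark CD33 ASO replicates 3, 7 and 10.

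A further label disagreed with the values. CD33 ASO replicate 3, the same mouse in both tissues, is labelled APP/PS1, but its signal of Thy1, the neuronal gene whose promoter drives the transgenes of this line, was 14.10 in cortex and 14.02 in hippocampus. WT arrays ranged from 14.08 to 14.24 and from 13.96 to 14.18, and the other CD33 ASO arrays from 14.77 to 14.93 and from 14.74 to 14.92. Its Cst7, a cystatin of plaque-associated microglia, was 5.33 and 5.38 against 9.49 to 10.66 and 8.03 to 9.29 on the other arrays of its group. Placed on a scale where the WT PBS mean is 0 and the APP/PS1 PBS mean is 1, the array labelled CD33 ASO replicate 3 lay at 0.21 in cortex and 0.22 in hippocampus, the other CD33 ASO arrays at 0.65 to 1.17 and 0.74 to 1.39. Groups were kept as labelled, so every direction given for CD33 ASO below is that of the arrays labelled so, these 3 mice included. Without replicate 3, Cd33 changed by -0.58 ± 0.12 in cortex (adjusted p = 0.0174) and -0.90 ± 0.11 in hippocampus (adjusted p = 9.45e-07). With mice measured in both tissues alone the changes were -0.79 ± 0.14 (adjusted p = 0.00187) and -1.06 ± 0.09 (adjusted p = 1.45e-11).

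**Figure D2:**
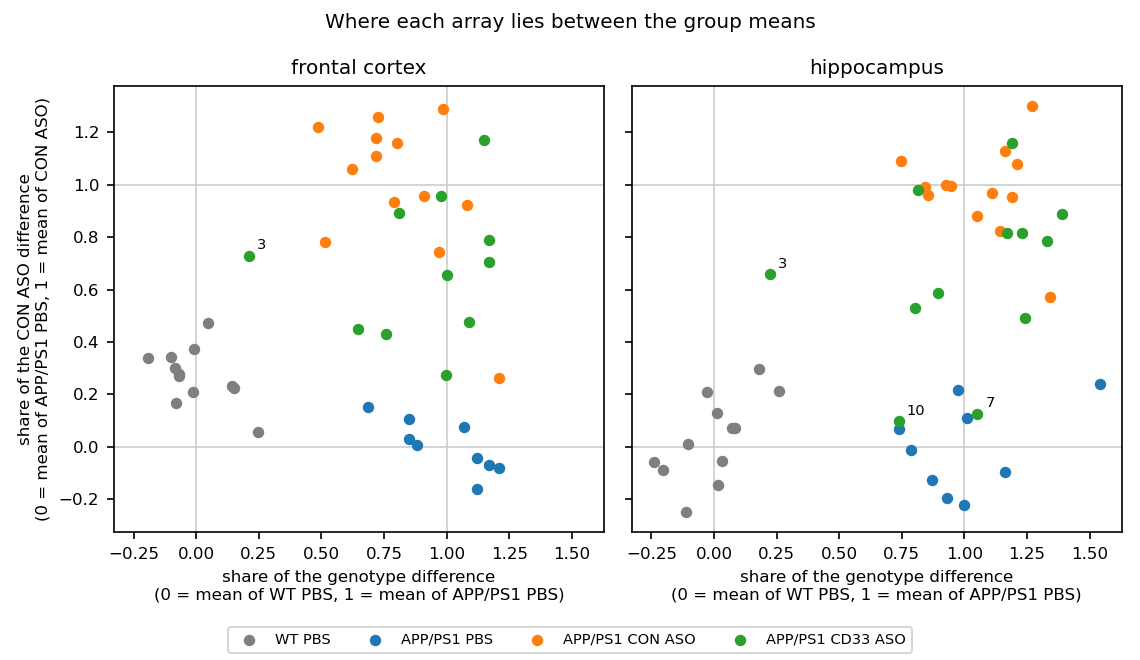
Position of each array between group means, as the median share of the genotype difference (horizontal) and of the CON ASO difference (vertical), both without units, over the probes that passed each comparison. CD33 ASO replicate 3 lies at 0.21 and 0.22 of the genotype difference in cortex and hippocampus, and hippocampal replicates 7 and 10 lie at 0.13 and 0.10 of the CON ASO difference.

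The first comparison set CD33 ASO against CON ASO within APP/PS1 mice, the contrast that leaves the CD33 sequence as the difference between treatments. In frontal cortex (n = 11 and 13) Fcna and Gpnmb were lower on the arrays labelled CD33 ASO. Fcna, a ficolin of macrophages, fell by 0.87 ± 0.14 on the log2 scale, 1.83-fold lower (adjusted p = 0.00105, detected on 8 of 11 against 12 of 13 arrays). Gpnmb, a glycoprotein of lipid-laden phagocytes and plaque-associated microglia, fell by 0.85 ± 0.17, 1.8-fold lower (adjusted p = 0.0171, both probes). The lysosome transport adaptor Fyco1 fell by 0.48 ± 0.10 (adjusted p = 0.0171) and Slc6a13, a GABA transporter of the meninges, by 0.41 ± 0.09 (adjusted p = 0.0488). Among those that rose besides Avil were the glycine cleavage enzyme Gldc (0.31 ± 0.06, adjusted p = 0.00811), the acyltransferase Mboat2 (0.32 ± 0.07, adjusted p = 0.0171) and Aspdh (0.42 ± 0.10, adjusted p = 0.0488).

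In all, 22 cortical probes passed, 10 higher and 12 lower, against 1405 at an unadjusted p under 0.05. The remaining named genes were smaller changes, of which Mfap3, Spg7, Kdm1b, Dctn4 and Hibadh rose by 0.18 to 0.31 and Cdk10, Retsat, Nrbp2, Pfdn2 and Bcl2l2 changed by -0.35 to -0.18. With chip as a block 43 probes passed (27 higher, 16 lower) and with day as a block 30, and 95.5% to 100% of the 22 had the same sign within each chip, 100% within each day. Here and below, such shares are of probes called over the same arrays. A high share follows largely from that choice and is not a separate test of batches. Within days 1 to 4 the fit passed 2, 1, 2 and 1 probes. With the compared groups alone 1 probe passed, higher, and each of the falls lost its call. The replicate number as a block, a fit that also left out arrays numbered above 9, gave 112 (79 higher, 33 lower). The fit without arrays of low weight gave 89 (56 higher, 33 lower). Median centring of the arrays gave 21 higher and 4 lower. Single arrays moved the count: without CON ASO replicate 1 it was 36, without CON ASO replicate 12 it was 58, and without CD33 ASO replicates 7 or 8 it was 11 or 12. Without CD33 ASO replicate 3 it was 28, 19 of them among the 22, and Aspdh, Nrbp2 and Slc6a13, at 0.42 ± 0.10, -0.22 ± 0.05 and -0.40 ± 0.10, no longer passed (adjusted p = 0.0616, 0.0616 and 0.0646).

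Of the gene lists fixed in advance, 9 of 33 shifted in cortex at a preset correlation and none with an estimated correlation. The plaque-associated microglia list was lower (median -0.14 over 32 genes, 1 fell, 2 adjusted over the list alone, adjusted p = 1.8e-06). Its adjusted p was 0.495 with an estimated correlation. Lgals3, the galectin of activated phagocytes, stood at -0.72 ± 0.23 (adjusted p = 0.249) and Trem2, the microglial lipid receptor, at -0.31 (adjusted p = 0.506). Pan-microglia genes (median -0.17 over 19, 0 called, adjusted p = 0.00648) and homeostatic microglia genes (-0.073 over 19, 0 called, adjusted p = 0.0148) lay lower, both at adjusted p = 0.764 with an estimated correlation. The CD33 family list (-0.018 over 16, of which Cd33 fell, adjusted p = 0.0103), perivascular and border macrophages (-0.17 over 9, adjusted p = 0.0103), interneurons (-0.10 over 13, adjusted p = 0.0103) and blood cells (-0.53 over 6, adjusted p = 0.0359) were lower, each at adjusted p = 0.3 with an estimated correlation. Lysosome genes (-0.053 over 27, adjusted p = 0.0241, 0.764 with an estimated correlation) were lower, and oligodendrocyte precursor genes (0.089 over 8, adjusted p = 0.0404, 0.364 with an estimated correlation) were higher. No member of the macrophage, interneuron, blood, lysosome or precursor lists passed over all genes by limma, which gave 1405 probes at an unadjusted p under 0.05, while 1 interneuron, 2 lysosome and 5 blood cell genes (1 higher, 4 lower) passed adjusted over the list alone.

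In hippocampus (n = 12 and 13) the same direction was seen for markers of macrophages at the brain's borders. Fcna fell by 1.33 ± 0.17, 2.51-fold lower (adjusted p = 2.27e-06, detected on 7 of 12 against 12 of 13 arrays), and Ms4a7, a marker of border macrophages, by 1.03 ± 0.17 (2.03-fold, adjusted p = 0.000545). The lipid droplet coat gene Plin4 fell by 1.27 ± 0.24 (2.41-fold, adjusted p = 0.00388), Lgals3 by 1.11 ± 0.23 (2.16-fold, adjusted p = 0.0228) and Gpnmb by 0.99 ± 0.16 (1.99-fold, adjusted p = 0.000496, both probes). Anpep, an aminopeptidase of pericytes and myeloid cells (-0.73 ± 0.13), the macrophage reductase Cbr2 (-0.66 ± 0.14), the lipocalin Apod (-0.49 ± 0.11) and the decarboxylase Ddc (-0.43 ± 0.08) were also lower. A pair of myelin genes fell, Mobp (-0.59 ± 0.10, adjusted p = 0.00146, 1 of 3 probes called and all 3 lower) and Hapln2 (-0.42 ± 0.10, adjusted p = 0.0446). Besides Avil, Czib (0.48 ± 0.08, adjusted p = 0.000253) and the mannose phosphate enzyme Pmm2 (0.32 ± 0.07, adjusted p = 0.0446) rose.

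In hippocampus 17 probes passed, 4 higher and 13 lower, against 618 at an unadjusted p under 0.05, and the count was 23 with chip and 15 with day as a block. Within each chip 94.1% to 100% of the 17 had the same sign and within each day 88.2% to 100%, and days 1 to 3 alone passed 2, 0 and 1 probes. Day 4 holds 1 CD33 ASO array, so its 52 probes, 3 of them among the 17, rest on a single mouse. With the compared groups alone 11 passed (2 higher, 9 lower). Without CON ASO replicate 6 the count was 10 and without CD33 ASO replicate 10 it was 11. Without CD33 ASO replicate 3 it was 15, all among the 17, and Hapln2 and Pmm2, at -0.43 ± 0.10 and 0.31 ± 0.07, no longer passed (adjusted p = 0.0574 and 0.0727). With mice measured in both tissues alone it was 15, 11 of them among the 17, and Pmm2, Apod, Cbr2 and Lgals3, at 0.29 ± 0.08, -0.46 ± 0.12, -0.63 ± 0.15 and -0.90 ± 0.22, no longer passed (adjusted p = 0.176, 0.154, 0.0783 and 0.145).

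The list of perivascular and border macrophages was lower in hippocampus (median -0.48 over 8 genes, 2 fell, 5 adjusted over the list alone, adjusted p = 1.09e-13 and 4.3e-04 with an estimated correlation). So were blood cell genes (-0.52 over 5, none called over all genes, 4 adjusted over the list alone, adjusted p = 3.38e-08 and 0.00804 with an estimated correlation). Folr2, the folate receptor of border macrophages, stood at -0.42 (adjusted p = 0.183) and the haem synthesis gene Alas2 at -0.90 (adjusted p = 0.479). By chip the macrophage median ran from -0.65 to -0.20 and the blood median from -1.21 to -0.17, and by day from -0.68 to -0.098 and from -1.50 to -0.24. With chip as a block the medians were -0.48 and -0.51, and with day -0.49 and -0.54. Markers of neighbouring tissue were lower beside them: choroid plexus and ependyma (-0.52 over 15, 0 called, adjusted p = 0.00478, 0.782 with an estimated correlation) and meninges and fibroblasts (-0.21 over 17, 0 called, 1 adjusted over the list alone, adjusted p = 1.39e-05, 0.51 with an estimated correlation). Pan-microglia genes lay at -0.074 (19 genes, 0 called, adjusted p = 0.019, 0.797 with an estimated correlation), and without both doubted sets of mice at 0.051 (adjusted p = 0.51). Orthologues of Alzheimer's disease risk genes lay at -0.029 (24 genes, Cd33 fell, 2 adjusted over the list alone, adjusted p = 0.0261, 0.51 with an estimated correlation). The plaque-associated list did not pass (-0.027 over 30, Gpnmb and Lgals3 fell, adjusted p = 0.0651). For 14 inflammatory cytokine and NF-kappaB genes (median 0.058, mean -0.011) and 13 Toll-like receptor genes (median 1.4e-04, mean -0.040) median and mean differed in sign.

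**Figure D3:**
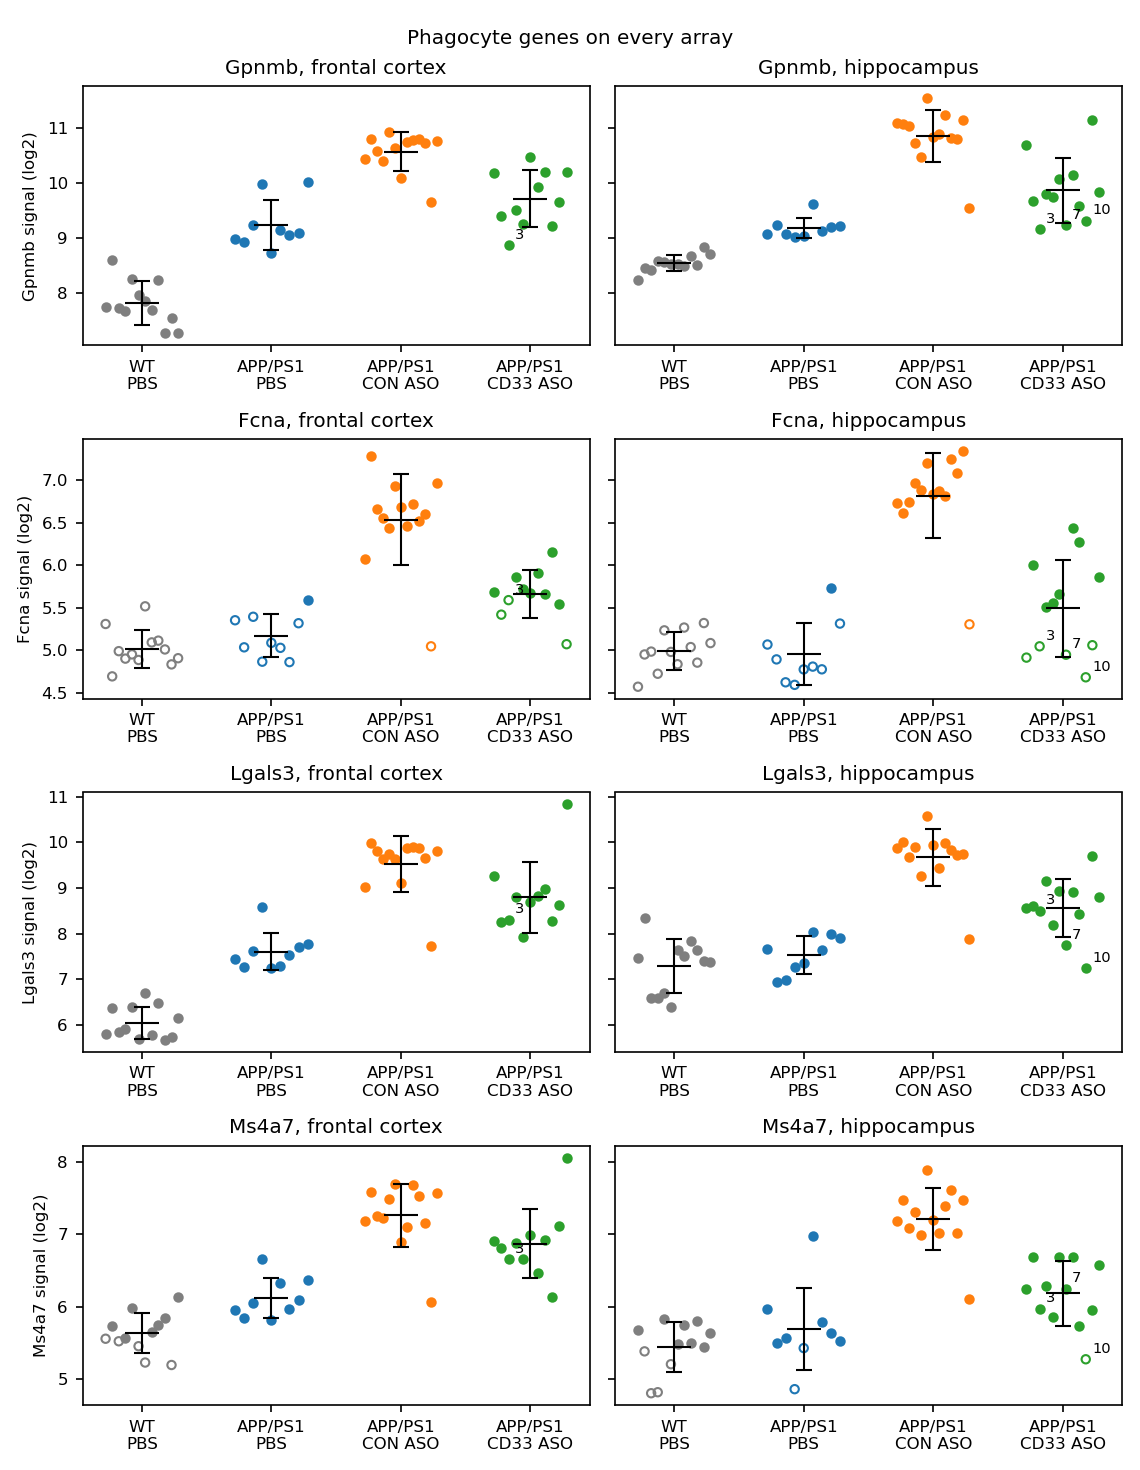
Log2 signal of Gpnmb, Fcna, Lgals3 and Ms4a7 on each array, by group and tissue; filled points were detected, open points were not, and bars are means with SD. In hippocampus all 4 genes were lower under CD33 ASO than under CON ASO, by 0.99 to 1.33 on the log2 scale.

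No probe showed a CD33 ASO effect that differed between the tissues by the interaction test in limma (0 of 14884 probes, 1365 at an unadjusted p under 0.05). Across the 10 CD33 ASO mice with both tissues, Cd33 in cortex and in hippocampus were not correlated (Pearson r = -0.0015, permutation p = 0.997; Spearman rho = -0.20, permutation p = 0.585). Without the pair of mice farthest from the median r was -0.44 (permutation p = 0.269). With day means removed r was 0.078, and no day held 6 of these mice.

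The second comparison, APP/PS1 PBS (n = 9) against WT PBS (n = 12), gave the effect of the transgenes. In cortex microglial genes rose most. Cst7 was detected on 9 of 9 APP/PS1 and 0 of 12 WT arrays, a difference of 5.09 ± 0.33 or at least 22.1-fold (adjusted p = 9.09e-16), and the chemokines Ccl3 (4.43 ± 0.25, at least 12.9-fold) and Ccl4 (4.20 ± 0.24, at least 12.7-fold) behaved alike. Trem2 rose 5.96-fold (2.58 ± 0.16), its signalling partner Tyrobp 5.74-fold (2.52 ± 0.15) and the astrocyte filament gene Gfap 5.93-fold (2.57 ± 0.16). Cd33 rose 1.94-fold (0.96 ± 0.15, adjusted p = 5.1e-06) and Thy1 1.59-fold (0.67 ± 0.05, adjusted p = 2.05e-14), while App was 1.1-fold lower (-0.14 ± 0.05, adjusted p = 0.0391). Probe sequences were not used here, so whether the App and Thy1 probes read the transgenes was not checked.

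In cortex 2764 probes passed, 1223 higher and 1541 lower, and the count was 3402 with chip and 2769 with day as a block, with 92% to 99% of them of the same sign within each chip and 96.8% to 99.6% within each day. Days 1 to 4 alone passed 0, 254, 665 and 456 probes. All 19 pan-microglia genes rose (median 1.54, adjusted p = 7.22e-45), among them the complement genes C1qa (1.77) and C1qb (1.56), with 17 of 19 homeostatic microglia genes (median 0.96, adjusted p = 9.5e-31), among them Olfml3 (1.56), Siglech (1.55) and Gpr34 (1.42). Of 32 plaque-associated genes 27 rose, 29 adjusted over the list alone (median 1.41, adjusted p = 7.59e-55), Cd52 by 2.98 and Ch25h, the cholesterol hydroxylase, by 2.79 (detected on 0 of 12 WT arrays, at least 4.45-fold). Interferon response genes rose in 22 of 27, 24 adjusted over the list alone (median 1.05, adjusted p = 1.09e-22). Ifi27l2a rose by 2.86 and Oasl2 by 2.10. Complement (5 of 7, median 1.55, adjusted p = 8.83e-14, C4b by 2.18), Toll-like receptors and nucleic acid sensors (10 of 13, 1.12, adjusted p = 4.47e-13, Tlr2 by 2.31) and cytokines and NF-kappaB (12 of 17, 0.71, adjusted p = 2.31e-14) rose as well. The lysosome list (23 of 27 rose and 1 fell, median 0.55, adjusted p = 3.16e-26) included Ctsz (1.84), Gusb (1.68) and Hexa (0.94). Of the CD33 family and its signalling, 7 of 16 rose and 1 fell, 8 and 1 adjusted over the list alone (median 0.15, adjusted p = 4.4e-07), with the phosphatase Ptpn6 at 1.80.

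Astrocyte and lipid genes moved with them in cortex. Of 20 reactive astrocyte genes 10 rose, 12 adjusted over the list alone (median 0.43, adjusted p = 5.13e-12), Osmr by 1.02. Of 17 astrocyte genes 7 rose, 8 adjusted over the list alone (median 0.16, adjusted p = 5.64e-05), with the water channel Aqp4 at 0.87 and Clu at 0.24. Lipid efflux and lipoprotein genes rose in 6 of 14 (median 0.23, adjusted p = 2.5e-06), Apoe by 0.32 ± 0.05 (1.25-fold, adjusted p = 2.71e-06) and Lpl by 0.67. Among risk gene orthologues 13 of 24 rose and 3 fell, 13 and 4 adjusted over the list alone (median 0.25, adjusted p = 1.85e-08), Grn by 1.23, Abi3 by 1.49 and Plcg2 by 1.10. The 13 lists named for cortex to this point held with an estimated correlation (adjusted p = 2.86e-04 to 0.0368). The others did not. These were antigen presentation (11 of 19 rose, 15 adjusted over the list alone, median 0.81, adjusted p = 1.98e-11, 0.107 with an estimated correlation), with B2m at 1.08, and perivascular macrophages (3 of 9 rose, 4 adjusted over the list alone, median 0.25, adjusted p = 0.00943, 0.121 estimated). Nor did cholesterol synthesis (5 of 15 rose, 7 adjusted over the list alone, 0.10, adjusted p = 0.0249, 0.364 estimated), with Stard4 at 0.47, endothelium and pericytes (3 of 22 rose, 0.12, adjusted p = 0.0221, 0.229 estimated) and oligodendrocyte precursors (2 of 8 rose, 3 adjusted over the list alone, 0.18, adjusted p = 0.0353, 0.149 estimated).

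The lists of immediate early and interneuron genes were lower in cortex at the preset correlation alone. The neuropeptide gene Adcyap1 fell by 0.80 ± 0.10 (1.74-fold lower, adjusted p = 5.7e-09). Of 20 immediate early genes 6 fell, 9 adjusted over the list alone (median -0.29, adjusted p = 7.28e-04, 0.144 with an estimated correlation), Fos by 0.68 ± 0.22 and Arc by 0.68. Of 13 interneuron genes 5 fell (median -0.24, adjusted p = 0.00149, 0.061 with an estimated correlation), among them Npy (-0.31), Sst (-0.30), Cck (-0.28) and Pvalb (-0.25). By chip the pan-microglia median ran from 1.22 to 1.81, the plaque-associated from 1.16 to 1.77, the interferon from 0.87 to 1.35, the lysosome from 0.38 to 0.67 and the reactive astrocyte from 0.26 to 0.55. By day they ran from 1.40 to 1.71, 1.08 to 1.64, 0.83 to 1.22, 0.42 to 0.72 and 0.32 to 0.46. As a block, chip gave 1.54, 1.42, 1.09, 0.54 and 0.44 and day 1.53, 1.40, 1.04, 0.55 and 0.42. No shift passed for neurons (-0.042, 1 rose and 3 fell of 20, adjusted p = 0.508), myelin (0.034, 3 of 15 rose, adjusted p = 0.149) or T, NK and B lymphocytes (0.0019 over 4, adjusted p = 0.853). Nor did one pass for striatum (-0.088 over 13, adjusted p = 0.602), hippocampal fields (0.033 over 12, adjusted p = 0.615) or p53 targets (-0.069, 1 of 14 fell, adjusted p = 0.533). The same held for the unfolded protein response (-0.043 over 19, adjusted p = 0.612), mitochondrial respiration (-0.060, 2 of 23 fell, adjusted p = 0.097) and proliferation (0.11, 1 of 10 rose, adjusted p = 0.0761). Amyloid precursor processing and clearance (2 rose and 2 fell of 18, adjusted p = 0.612) had a median of -0.028 and a mean of 0.029.

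In hippocampus the transgenes raised microglial genes as well. Cst7 rose by 3.63 ± 0.26 (adjusted p = 2.9e-14, detected on 9 of 9 against 1 of 12 arrays, so measured from background), Trem2 3.54-fold (1.82 ± 0.14), Tyrobp 3.24-fold (1.70) and Gfap 2.19-fold (1.13 ± 0.16). Cd33 rose 1.42-fold (0.51 ± 0.12, adjusted p = 0.00471) and Thy1 1.68-fold (0.75 ± 0.05, adjusted p = 2.9e-14), and App stood at -0.18 (adjusted p = 0.127). The proteasome activator Psme2 fell by 0.63 ± 0.08 (1.54-fold lower, adjusted p = 1.79e-07) and the chemokine Cxcl12 by 0.60 (1.51-fold lower, adjusted p = 0.0423). In all 360 probes passed, 263 higher and 97 lower. The count was 691 with chip as a block (398 higher, 293 lower) and 343 with day, with 97.5% to 100% of the 360 of the same sign within each chip and 98.9% to 100% within each day. Days 1 to 4 alone passed 0, 23, 86 and 63. Without APP/PS1 PBS replicate 5 the count was 237 and without replicate 6 it was 239.

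Of the hippocampal lists 20 shifted, 15 higher and 5 lower, and 9 held with an estimated correlation (adjusted p = 3.44e-05 to 0.0418). These were pan-microglia (15 of 19 rose, 17 adjusted over the list alone, median 0.92, adjusted p = 9.09e-52), homeostatic microglia (12 of 19, 16 adjusted over the list alone, 0.51, adjusted p = 1.53e-31), plaque-associated microglia (18 of 30, 23 adjusted over the list alone, 0.74, adjusted p = 9.41e-48), the CD33 family (7 of 15, 7 higher and 1 lower adjusted over the list alone, 0.11, adjusted p = 6.32e-10). They included Toll-like receptors (7 of 13, 0.37, adjusted p = 5.27e-13), cytokines (6 of 14, 8 adjusted over the list alone, 0.40, adjusted p = 1.89e-13), lysosome (9 of 27, 15 adjusted over the list alone, 0.19, adjusted p = 3.55e-13), risk gene orthologues (6 of 24, 11 adjusted over the list alone, 0.20, adjusted p = 2.52e-09) and complement (4 of 9, 0.044, adjusted p = 3.48e-06). The microglial scavenger gene Fcrls rose by 1.12, Ly86 by 1.27 and C4b by 1.14. By chip the pan-microglia median ran from 0.78 to 1.08, the plaque-associated from 0.56 to 1.14 and the complement from -0.020 to 0.43. By day they ran from 0.83 to 1.18, 0.66 to 0.86 and -0.041 to 0.29, the complement median being above 0 on 2 of 4 days. With chip as a block the first pair of medians was 0.91 and 0.74, and with day 0.91 and 0.73. Interferon response (6 of 27 rose, 11 adjusted over the list alone, 0.33), antigen presentation (8 of 19 rose, 0.26) and reactive astrocytes (5 of 19 rose, 8 adjusted over the list alone, 0.31) shifted at adjusted p = 5.02e-11, 3.77e-07 and 1.21e-07, and with an estimated correlation at adjusted p = 0.109, 0.111 and 0.097. Cholesterol synthesis (2 of 15 rose, 6 adjusted over the list alone, 0.20), lipid efflux (1 of 14 rose, 0.053) and neurons (1 of 20, Thy1, rose, 0.045) had adjusted p = 1.96e-04, 0.0196 and 0.0177, and 0.182, 0.184 and 0.116 with an estimated correlation. Lower were immediate early genes (0 of 20 called, -0.22, adjusted p = 8.82e-05, 0.0993 estimated), interneurons (1 of 13 fell, 3 adjusted over the list alone, -0.15, adjusted p = 0.00765, 0.0993 estimated) and mitochondrial respiration (2 of 23 fell, 6 adjusted over the list alone, -0.012, adjusted p = 0.0219, 0.32 estimated). Markers of neighbouring tissue were also lower, choroid plexus and ependyma (0 of 15 called, -0.93, adjusted p = 1.96e-04, 0.32 estimated) and meninges (0 of 17 called, -0.28, adjusted p = 0.00765, 0.411 estimated).

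The genotype effect differed between the tissues at 503 probes by the interaction test, 153 higher and 350 lower in hippocampus. Gfap differed most clearly (-1.49 ± 0.21, adjusted p = 2.14e-06), followed by Anxa3 (-0.72 ± 0.11, adjusted p = 1.03e-05), the TGF-beta receptor gene Tgfbr2 (-0.80 ± 0.12, adjusted p = 1.57e-05), Rnaset2b (-0.68, adjusted p = 1.76e-05) and Heatr5a (-0.70, adjusted p = 3.37e-05). Tgfbr2 rose by 1.26 in cortex and 0.49 in hippocampus.

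**Figure D4:**
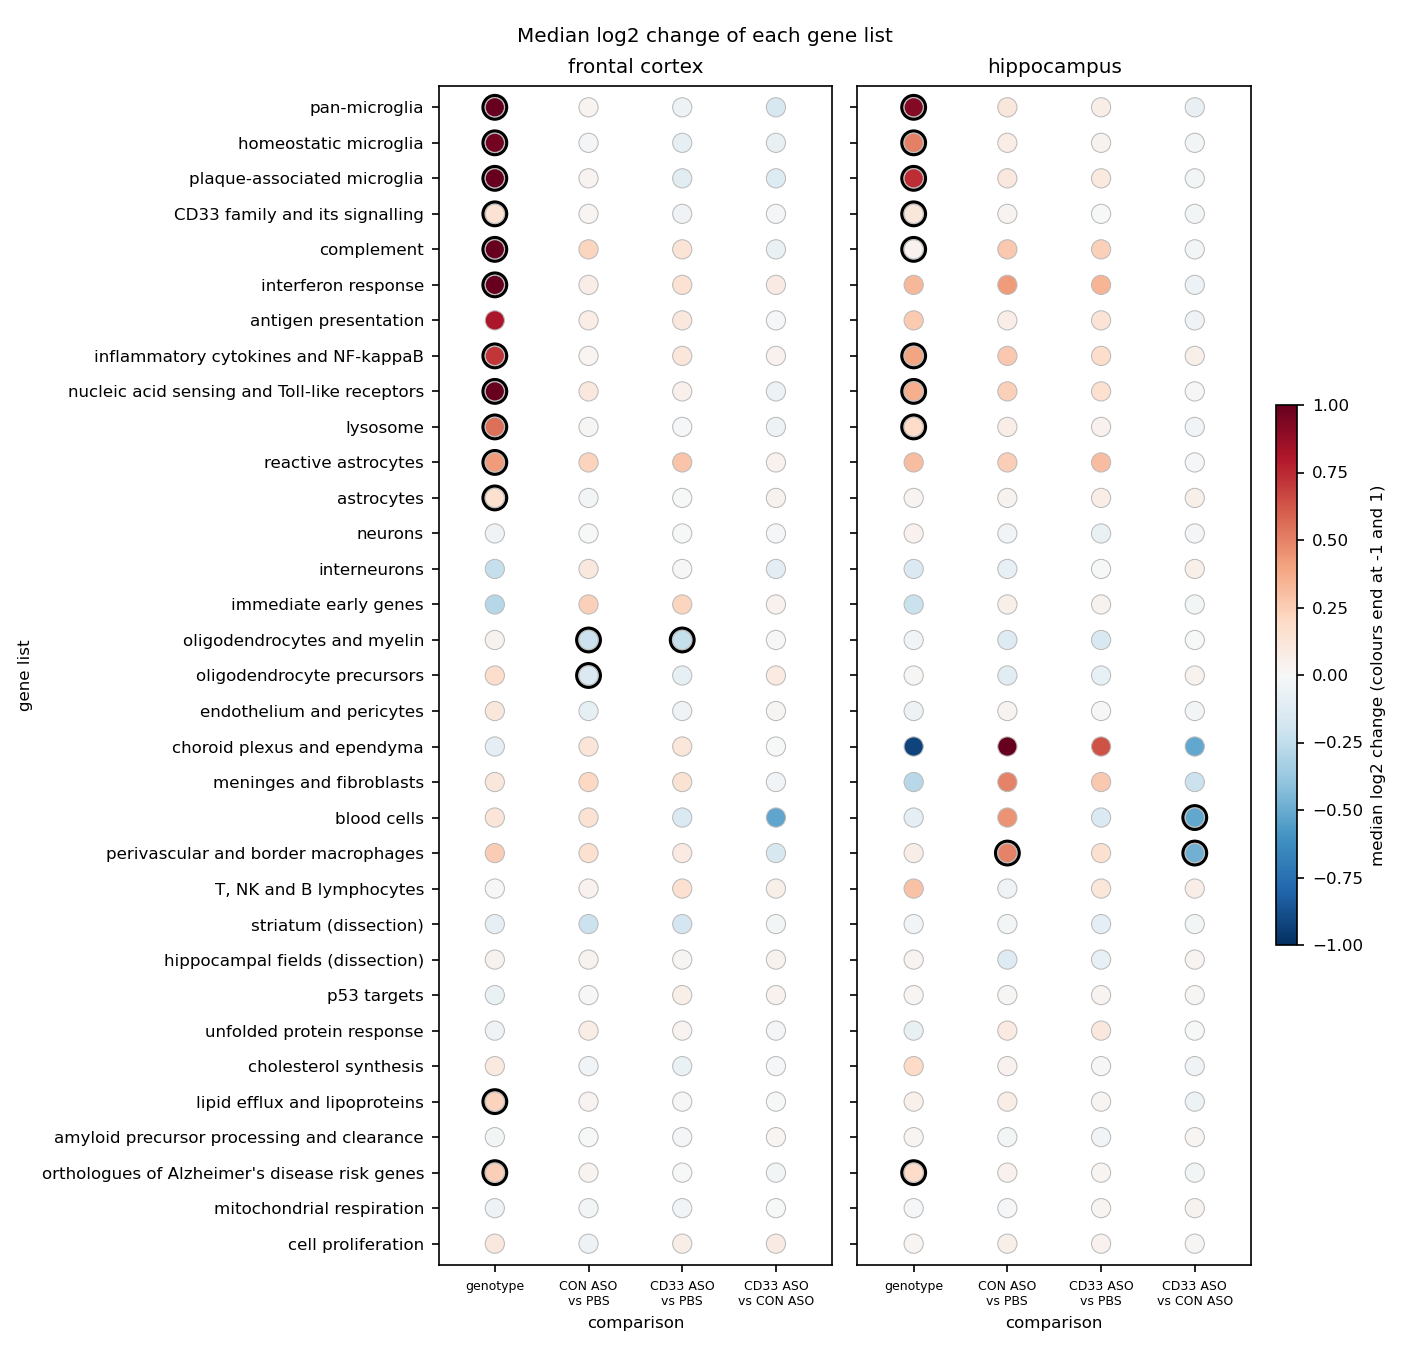
Median log2 change of each gene list in the 4 comparisons of each tissue, as colour from -1 (blue) to 1 (red); black rings mark shifts that held with an estimated correlation. In the genotype comparison 13 lists held in cortex and 9 in hippocampus, and under CD33 ASO against CON ASO 0 and 2.

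The third comparison, CON ASO (n = 13) against PBS (n = 9) in APP/PS1 mice, showed what an oligonucleotide without a target did. Plin4, Lgals3, Fcna, Gpnmb and Ms4a7 rose in both tissues. In cortex Plin4 rose 4.28-fold (2.10 ± 0.32, adjusted p = 8.31e-05), Lgals3 3.76-fold (1.91 ± 0.24, adjusted p = 3.18e-06), Gpnmb 2.51-fold (1.33 ± 0.18), Wfdc17 2.29-fold (1.20 ± 0.14) and Ms4a7 2.21-fold (1.14 ± 0.16). In hippocampus the rises were 4.27-fold for Plin4, 4.42-fold for Lgals3 (2.14 ± 0.25, adjusted p = 3.1e-07), 3.21-fold for Gpnmb and 2.86-fold for Ms4a7. Fcna, detected on 12 of 13 against 1 of 9 arrays in each tissue and so measured from background, rose by 1.37 ± 0.15 in cortex and 1.87 ± 0.19 in hippocampus (adjusted p = 2.39e-09). Opalin, a membrane protein of mature oligodendrocytes, was 1.83-fold lower in cortex (-0.87 ± 0.13, adjusted p = 8.34e-05) and 1.64-fold lower in hippocampus (-0.71 ± 0.17, adjusted p = 0.0232).

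In cortex 7 of 15 oligodendrocyte and myelin genes fell, 10 adjusted over the list alone (median -0.21, adjusted p = 2.45e-12, 0.0183 with an estimated correlation), among them Mag (-0.35 ± 0.08), Fa2h (-0.34) and Mbp (-0.17, 1 of 3 probes called). Outside that list Pllp stood at -0.60 ± 0.08 (adjusted p = 1.03e-05) and Bcas1, of the precursor list, at -0.34. Of 8 oligodendrocyte precursor genes 2 fell, 3 adjusted over the list alone (median -0.15, adjusted p = 2.7e-04, 0.0498 with an estimated correlation), among them Enpp6 (-0.90 ± 0.18, adjusted p = 0.00299). By chip the myelin median ran from -0.41 to -0.077 and the precursor median from -0.46 to 0.0040, and by day from -0.42 to -0.046 and from -0.26 to -0.17. With chip as a block they were -0.19 and -0.15, and with day -0.21 and -0.15. The striatum list, which reads how much striatum a block of cortex holds, was lower beside them (median -0.22 over 13, none called over all genes, 4 adjusted over the list alone, adjusted p = 1.72e-04, 0.379 with an estimated correlation). Reactive astrocyte genes (2 of 20 rose, 0.23, adjusted p = 1.12e-04, 0.343 with an estimated correlation), with Hspb1 at 0.35, were higher. So were immediate early genes (1 of 20, Jun, rose, 4 adjusted over the list alone, 0.24, adjusted p = 1.12e-04, 0.239 estimated) and the unfolded protein response (3 of 19 rose, 5 adjusted over the list alone, 0.078, adjusted p = 0.0114, 0.326 estimated), with Xbp1 at 0.25 ± 0.05. Perivascular macrophages (2 of 9 rose, 3 adjusted over the list alone, 0.16, adjusted p = 0.00209, 0.216 estimated), meninges and fibroblasts (1 of 17, Col1a1, rose, 5 adjusted over the list alone, 0.21, adjusted p = 1.12e-04, 0.326 estimated) and complement (0 of 7 called, 1 adjusted over the list alone, 0.22, adjusted p = 0.0114, 0.454 estimated) were higher, and endothelium and pericytes (0 of 22 called, 1 higher and 2 lower adjusted over the list alone, -0.092, adjusted p = 0.0358, 0.379 estimated) lower. Pan-microglia genes (0.027, adjusted p = 0.168) and plaque-associated genes (0.026, adjusted p = 0.0939) did not shift past the threshold, and homeostatic microglia genes (adjusted p = 0.705) had a median of -0.018 and a mean of 6.64e-04.

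In hippocampus 17 lists shifted under CON ASO, 15 higher and 2 lower, and perivascular and border macrophages held with an estimated correlation (4 of 8 rose, 5 higher and 1 lower adjusted over the list alone, median 0.50, adjusted p = 4.48e-09, 0.0117 estimated), with Cbr2 at 0.89 and Folr2 at 0.58 (detected on 10 against 1 arrays). By chip that median ran from 0.18 to 0.85 and by day from -0.054 to 0.89, above 0 on 3 of 4 days, and it was 0.49 with either as a block. Interferon response genes were higher (4 of 27 rose, 14 adjusted over the list alone, 0.42, adjusted p = 1.82e-13, 0.122 with an estimated correlation), with Ifitm3 at 0.67, Rsad2 at 0.65 and Isg15 at 0.60. So was complement (2 of 9 rose, 4 adjusted over the list alone, 0.27, adjusted p = 3.12e-07, 0.078 estimated), with C2 at 1.26 and Serping1 at 0.92. Reactive astrocytes (5 of 19 rose, 8 adjusted over the list alone, 0.25, adjusted p = 8.28e-10, 0.119 estimated), pan-microglia (1 of 19 rose, 6 higher and 1 lower adjusted over the list alone, 0.11, adjusted p = 2.5e-04, 0.323 estimated), plaque-associated microglia (3 of 30 rose, 4 higher and 1 lower adjusted over the list alone, 0.11, adjusted p = 2.59e-05, 0.224 estimated) and the unfolded protein response (2 of 16 rose, 5 higher and 2 lower adjusted over the list alone, 0.089, adjusted p = 0.00673, 0.143 estimated), with Xbp1 at 0.32, shifted too. The interneuron peptide gene Cort fell by 1.19 ± 0.23 (2.27-fold lower, adjusted p = 0.00259). Interneuron (2 of 13 fell, 5 adjusted over the list alone, -0.080, adjusted p = 0.00522, 0.122 estimated) and myelin genes (3 of 15 fell, 8 adjusted over the list alone, -0.13, adjusted p = 1.48e-06, 0.14 estimated) were lower. Neighbouring tissue and blood moved in the same samples: choroid plexus and ependyma (1 of 15, Rarres2, rose, 1.16, adjusted p = 4.3e-07, 0.224 estimated), meninges (0 of 17 called, 9 adjusted over the list alone, 0.50, adjusted p = 3.21e-10, 0.122 estimated) and blood cells (0 of 5 called, 1 adjusted over the list alone, 0.45, adjusted p = 7.44e-04, 0.122 estimated). The remaining shifted lists, homeostatic microglia, antigen presentation, cytokines, Toll-like receptors and lysosome, had medians of 0.072, 0.068, 0.27, 0.24 and 0.066 and lost the call (adjusted p = 0.328, 0.376, 0.188, 0.224 and 0.274 with an estimated correlation).

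Under CON ASO 377 cortical probes passed against PBS, 165 higher and 212 lower, and 187 in hippocampus, 119 higher and 68 lower. Chip as a block gave 519 in cortex (217 higher, 302 lower) and 323 in hippocampus (153 higher, 170 lower), and day 415 and 185. Within chips 89.1% to 99.2% of the cortical and 94.1% to 100% of the hippocampal probes had the same sign, and within days 96.6% to 100% and 96.3% to 100%. Days 1 to 4 alone passed 3, 0, 2 and 6 in cortex and 6, 0, 1 and 32 in hippocampus. Median centring gave 69 higher and 306 lower in cortex, and 104 higher and 24 lower in hippocampus. The striatum covariate gave 116 in cortex and the choroid plexus covariate 117 in hippocampus, while array weights gave 752 and 477. With the replicate number as a block, over arrays numbered up to 9 alone, 1021 and 415 passed. The cortical count was 233, 223 or 245 without APP/PS1 PBS replicate 4, 7 or 8 and 586 without CON ASO replicate 12, and the hippocampal count was 115, 108 or 116 without APP/PS1 PBS replicate 3, 4 or 7. CON ASO effects differed between tissues at 10 probes by the interaction test, 9 of them lower in hippocampus, with Tuba3a (-0.67), Rap2a (-0.36), Crhbp (-0.62) and Ak5 (-0.34) among the smallest p (adjusted p = 0.0284, 0.0284, 0.0304 and 0.0304). The 1 higher there was a clone without a gene name (0.88, adjusted p = 0.0284).

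The fourth comparison set CD33 ASO against PBS in APP/PS1 mice (9 PBS mice). On the arrays labelled CD33 ASO, Cd33 fell by 0.73 ± 0.16 in cortex (adjusted p = 0.0074) and by 0.89 ± 0.12 in hippocampus (adjusted p = 7.1e-06). Avil rose by at least 1.95-fold in cortex (1.57 ± 0.14, adjusted p = 2.11e-11) and by 1.58 ± 0.21 on the log2 scale in hippocampus (detected on 10 of 12 against 1 of 9 arrays, so measured from background). Lgals3 rose 2.27-fold in cortex (1.19 ± 0.25, adjusted p = 0.0074) and 2.04-fold in hippocampus (1.03 ± 0.25, adjusted p = 0.048), and Wfdc17 2.21-fold in cortex and by 1.12 in hippocampus, where it was detected on 3 of 9 PBS arrays. The Fc receptor gene Fcgr4 rose 2.75-fold in hippocampus (1.46 ± 0.29, adjusted p = 0.0141) and Ms4a7 1.68-fold in cortex (adjusted p = 0.00948). Opalin fell by 0.98 ± 0.14 in cortex and by 0.80 ± 0.18 in hippocampus, and the myelin surface gene Mog by 0.52 (adjusted p = 0.0114) and 0.62 ± 0.14 (adjusted p = 0.0274). Cort was 2.32-fold lower in hippocampus (-1.21 ± 0.24, adjusted p = 0.0102).

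Myelin genes were the cortical list that held with an estimated correlation in this comparison (6 of 15 fell, 11 adjusted over the list alone, median -0.24, adjusted p = 1.23e-14, 0.00667 estimated), with Mag (-0.34), Qdpr (-0.35) and Cldn11 (-0.24). By chip the median ran from -0.33 to -0.10 and by day from -0.31 to -0.23, and with chip or day as a block it was -0.24. The striatum list was lower beside it (1 of 13, Scn4b, fell, -0.18, adjusted p = 1.54e-05, 0.42 with an estimated correlation), as was the CD33 family (Cd33 and Mag fell of 16, -0.042, adjusted p = 0.0269, 0.311 estimated). Immediate early genes (1 of 20 rose, 4 adjusted over the list alone, 0.23, adjusted p = 2.32e-05, 0.311 estimated), reactive astrocytes (1 of 20 rose, 9 higher and 1 lower adjusted over the list alone, 0.29, adjusted p = 1.53e-04, 0.42 estimated) and meninges (1 of 17 rose, 0.14, adjusted p = 0.0174, 0.566 estimated) were higher. In hippocampus 13 lists shifted and none held with an estimated correlation: reactive astrocytes (1 of 19 rose, 5 adjusted over the list alone, 0.31, adjusted p = 1.05e-07, 0.187 estimated), interferon response (0 of 27 called, 11 adjusted over the list alone, 0.34, adjusted p = 2.32e-10, 0.227 estimated), complement (0 of 9 called, 1 adjusted over the list alone, 0.24, adjusted p = 9.05e-05, 0.187 estimated), plaque-associated microglia (1 of 30 rose, 2 adjusted over the list alone, 0.097, adjusted p = 0.00419, 0.568 estimated) were higher. So were 7 others, choroid plexus and ependyma (0.64 over 15) and meninges (0.27 over 17) among them, at adjusted p = 0.222 to 0.603 with an estimated correlation. Myelin (3 of 15 fell, 8 adjusted over the list alone, -0.16, adjusted p = 3.85e-07, 0.187 estimated) and neurons (0 of 20 called, -0.068, adjusted p = 0.00722, 0.187 estimated) were lower.

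Against PBS, 195 cortical probes passed, 74 higher and 121 lower, and 73 in hippocampus, 26 higher and 47 lower. Chip as a block gave 290 in cortex and 183 in hippocampus (70 higher, 113 lower), and day 207 and 78. Within chips 91.8% to 100% and 94.5% to 100% of them had the same sign, and within days 95.9% to 100% and 100%. With the compared groups alone 90 and 7 passed (3 higher and 4 lower in hippocampus), and with no filter 145 and 28. The striatum covariate gave 56 in cortex. Days 1 to 4 alone passed 0, 2, 0 and 170 in cortex, and days 1 to 3 alone 2, 0 and 0 in hippocampus. Day 4 holds 2 cortical CD33 ASO arrays, with 48 of its 170 among the 195, and 1 hippocampal array, so its 174 there, 15 of them among the 73, rest on a single mouse. Median centring gave 7 higher and 7 lower in hippocampus. The cortical count was 126 without APP/PS1 PBS replicate 3 and 115 without CD33 ASO replicate 8. The hippocampal count was 25, 34, 34, 152, 125, 17 or 39 without CD33 ASO replicate 1, 4, 6, 7, 10, 11 or 12, and 30, 22, 28, 30 or 41 without APP/PS1 PBS replicate 3, 4, 5, 7 or 9. Without CD33 ASO replicate 3 the counts were 192 in cortex and 61 in hippocampus, with 171 and 52 shared, and hippocampal Lgals3, hardly changed at 1.04 ± 0.26, no longer passed (adjusted p = 0.0574). With mice measured in both tissues alone the hippocampal count was 253, 72 of them among the 73. The effect differed between tissues at 7 probes by the interaction test, with Galnt9, Lgi1, Rtl3, Rap2a and Fgf5 of smallest p (adjusted p = 0.0478), and at 0 probes without replicate 3.

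Both oligonucleotides were compared with the same PBS mice, so their changes share chance values. Across probes, which are not independent replicates, the changes correlated at 0.634 in cortex and 0.763 in hippocampus, where unchanged groups simulated against the same controls gave 0.555 and 0.584 on average and up to 0.836 and 0.797, so both values lie inside the simulated range. The covariance was 0.0109 in cortex against 0.0058 simulated, a difference of 0.0051, and 0.017 in hippocampus against 0.0072, a difference of 0.0097. With the PBS mice split between the comparisons it was 0.0059 and 0.0103, and the correlation 0.286 and 0.37. In cortex 28 probes rose and 63 fell under both, where independent lists would share 0.851 and 1.79, simulated groups shared 0, and split controls gave 2.05 and 6.1. In hippocampus the counts were 14 and 25, against 0.214 and 0.221, 0, and 0.05 and 0.95. No probe passed in opposite directions in either tissue by limma, with 1768 and 1800 probes at an unadjusted p under 0.05 for CD33 ASO.

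Genes changed by the transgenes were followed under CD33 ASO against CON ASO. In cortex those that had risen had a median change of 0.024 (camera p = 0.0449, 0.651 with an estimated correlation), and those that had fallen -0.040 (p = 1.92e-08, 0.129 estimated), with 28.9% of these moving back toward WT. In hippocampus those that had risen stood at -0.024 (p = 5.69e-04, 0.5 estimated; 62.4% moving back) and those that had fallen at 0.052 (p = 4.64e-05, 0.351 estimated; 80.4% moving back). With chip as a block the 4 medians were 0.022, -0.041, -0.032 and 0.058, and with day 0.032, -0.032, -0.012 and 0.052. Replicate 3 bears on these values: without it the cortical medians were 0.064 and -0.053, and the hippocampal ones 0.017, of the opposite sign, and 0.036. The estimated p was then 0.133 and 0.0458 in cortex, so that the genes that had fallen passed, and 0.861 and 0.5 in hippocampus. With both exclusions it was 0.0661 for the cortical genes that had fallen.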

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

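The tests of CD33 ASO replicate 3, of the genes lower under CD33 ASO and of the myelin genes were chosen only after the results were seen. Genotype effects differed between cortex and hippocampus at 503 probes, CON ASO effects at 10 and CD33 ASO effects against PBS at 7, by the interaction test. Between tissues the genotype effect on Gfap was -1.49, on Anxa3 -0.72, on Tgfbr2 -0.80, on Rnaset2b -0.68 and on Heatr5a -0.70 (hippocampus minus cortex, log2), the CON ASO effect on Tuba3a -0.67, on Rap2a -0.36, on Crhbp -0.62, on Ak5 -0.34 and on a clone without a gene name 0.88 (-0.46 in cortex, 0.42 in hippocampus), and the CD33 ASO effect against PBS on Galnt9 -0.38, on Lgi1 -0.25, on Rtl3 -0.71, on Rap2a -0.35 and on Fgf5 -0.57. In the groups of 9 APP/PS1 PBS arrays, 28 of 237 gene and tissue sets held an array far from the others, where chance gives about 1 in 20. Hippocampal replicate 6 was the highest in 15 of them, at log2 signals of 10.78 for Anxa3, 10.82 for C1qa, 12.54 for C1qb, 11.90 for C4b, 14.44 for Clu, 8.22 for Fcgr4, 9.62 for Gpnmb, 11.89 for Ifitm3, 7.26 for Lcn2, 10.65 for Ly86, 10.52 for Lyz2, 9.10 for Ptpn6, 10.37 for Tgfbr2, 7.88 for Tlr2 and 10.94 for Trem2. In cortex replicate 2 stood low for Cst7 (9.02), Czib (9.50) and Fcrls (10.19), replicate 1 low for Fyco1 (8.05) and high for Opalin (11.01), replicate 4 high for Lcn2 (5.77) and Lgals3 (8.58), and replicate 5 high for Folr2 (5.70) and low for Pmm2 (8.48). In hippocampus replicate 1 stood high for Avil (5.62) and low for Jun (9.59), replicate 9 high for Ccno (7.71) and replicate 5 high for Tuba3a (7.04).

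A wrong genotype label may explain CD33 ASO replicate 3. No WT mouse of the series received an oligonucleotide, so where one would lie is not known. On the scale from the WT PBS mean at 0 to the APP/PS1 PBS mean at 1, replicate 3 lay at 0.21 in cortex and 0.222 in hippocampus. Both values lie within the range of WT PBS arrays. Its Avil (6.50 and 6.83) lay in the range of its treatment group, and its Cd33 (5.05 and 5.32) was the lowest of that group in cortex. A swap with a WT mouse of the series is argued against, since no WT PBS array lay above 0.248 in cortex or 0.26 in hippocampus. An effect of the oligonucleotide is argued against by the other CD33 ASO arrays, none below 0.646 or 0.737.

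The genes lower under CD33 ASO than under CON ASO may be a response to the control oligonucleotide that the CD33 oligonucleotide gives less of. Of the 11 cortical probes lower apart from Cd33, 7 lay above PBS under CON ASO, 4 of them called. Under CD33 ASO 5 (both for Cdk10, and those for Nrbp2, Bcl2l2 and Fyco1) passed below PBS and 0 above, with none of the 5 called under CON ASO (-0.16 to 0.025). The probes were chosen for the difference between these same CD33 ASO and CON ASO arrays. That choice favours low values in the first group and high values in the second, so counts against PBS do not decide the question. In hippocampus all 12 lay above PBS under CON ASO, 9 of them called. Under CD33 ASO 9 of 12 were higher than PBS, but 1 passed above (Lgals3, adjusted p = 0.048) and 1 below (Mobp, -0.49, adjusted p = 0.0288). A lesser response to the CD33 oligonucleotide stays open in both tissues. Choroid plexus tissue, as far as its list mean reads it, is argued against as the whole cause. With that mean as a covariate the hippocampal median went from -0.72 to -0.689 (SE 0.15 and 0.14), and 10 of 12 still passed. The biological alternative, an effect of less CD33, was not tested apart from the oligonucleotide and stays open.

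Myelin genes were lower in cortex under either oligonucleotide. Striatal tissue in the samples, as far as the striatum list mean reads it, is argued against as the whole cause. With that covariate the myelin list median went from -0.211 to -0.166 under CON ASO (p = 9.02e-04 with an estimated correlation) and from -0.237 to -0.21 under CD33 ASO (p = 3.3e-04). The genes called went from 7 to 3 and from 6 to 2, as changes shrank and median SE rose from 0.0832 to 0.0881 and from 0.0862 to 0.0916. Other differences in dissection were not tested, and an unusual PBS group could not be excluded. Against WT PBS, which has another genotype, the list stood at -0.178 under CON ASO and -0.203 under CD33 ASO, with 13 and 14 of 15 genes lower, where p was 0.00124 and 8.33e-04 at the preset correlation but 0.114 and 0.102 with an estimated correlation. An effect of oligonucleotides as such stays open, since both groups that received one share it.

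Among 100 splits of the samples, the real one included, few gave as many probes as the real one. For CD33 ASO against CON ASO in both tissues and against PBS in cortex, other splits called more probes, so chance is not excluded there. As many probes passed in 1 split for genotype in cortex (2764, highest other 0), 1 in hippocampus (360, highest other 312), 1 for CON ASO against PBS in cortex (377, highest other 84), 1 in hippocampus (187, highest other 1), 2 for CD33 ASO against PBS in cortex (195, highest other 631), 1 in hippocampus (73, highest other 39), 3 for CD33 ASO against CON ASO in cortex (22, highest other 252) and 3 in hippocampus (17, highest other 148). The splits with 252, 148 and 631 call several times the real count, and what those splits share was not tested. Differences between tissues were as many in 1 split for genotype (503, highest other 1), 2 for CON ASO (10, highest other 441) and 2 for CD33 ASO against PBS (7, highest other 61). What the splits with 441 and 61 share was not tested either. For CD33 ASO against CON ASO the real count was 0 by limma (1365 unadjusted, highest other 273). All 100 splits match a count of 0 by construction, so the splits decide nothing there.

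For list shifts at the preset correlation few splits were as high for genotype, 4 in cortex (20 lists, highest other 21) and 2 in hippocampus (20, highest other 21). More were as high for CD33 ASO against CON ASO, with 52 splits in cortex (9, highest other 20) and 61 in hippocampus (6, highest other 17). The same held for CON ASO against PBS, with 10 (10, highest other 18) and 7 (17, highest other 21), and for CD33 ASO against PBS, with 83 (6, highest other 21) and 27 (13, highest other 20). Chance was not excluded for these. Nor was it excluded for the genes changed by the transgenes, followed under CD33 ASO. In cortex 64 splits gave as large a median for those raised (0.024, highest other 0.125) and 19 for those lowered (size 0.040, highest other 0.068). In hippocampus 76 (size 0.024, highest other 0.187) and 35 did (0.052, highest other 0.169).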

How the results depend on the processing

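The fits without arrays of low weight, with a striatum or choroid plexus covariate, without CD33 ASO replicate 3, with mice of both tissues alone and with both exclusions were chosen only after the results were seen. Of 515 values of named genes, 8151 refits stayed on the same side of the threshold, 346 lost the call, 197 gained it and 0 reversed. Of 101 list shifts at the preset correlation, 1183 refits stayed, 127 lost the call and 3 reversed. With the submitters' value table, 509 named genes, all 101 list shifts and all 27 other results stayed. The cause was not tested for any change below unless named, and every fit is limited where signals lie near background, as for Cd33 in hippocampus.

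The cortical fall of Cd33 kept its direction in all fits but lost its call without background correction (-0.94, adjusted p = 0.0507) and with the compared groups alone (-0.71, adjusted p = 0.14). The last fit has fewer samples and a larger SE, 0.162 against 0.143. Cortical Cd33 spread more under CD33 ASO (SD 0.563) than under CON ASO (0.256), in APP/PS1 PBS (0.241) or in WT mice (0.297). Leaving out 1 array at a time gave -0.79 to -0.58 in cortex and -0.99 to -0.87 in hippocampus. The cortical genotype count kept within 1.5 times in every fit (2242 to 3123 without single arrays). The hippocampal one, 360, was 691 with chip as a block and 237 to 474 without single arrays. For CD33 ASO against CON ASO the cortical count, 22, was 42 with array weights, 43 with chip as a block, 1 with the compared groups alone, 89 without arrays of low weight and 11 to 58 without single arrays. The hippocampal count, 17, was 7 without background correction, 11 with the compared groups alone, 11 with the stricter filter and 10 to 19 without single arrays. For CON ASO against PBS the cortical count, 377, was 752 with array weights, 226 with no filter, 652 without arrays of low weight, 116 with the striatum covariate and 223 to 586 without single arrays. The hippocampal count, 187, was 477 with array weights, 323 with chip as a block, 117 with the choroid plexus covariate and 108 to 237 without single arrays. For CD33 ASO against PBS the cortical count, 195, was 129 with median centring, 90 with the compared groups alone, 56 with the striatum covariate, 128 with both exclusions and 115 to 248 without single arrays. The hippocampal count, 73, was 112 with array weights, 183 with chip as a block, 14 with median centring, 28 with no filter, 7 with the compared groups alone, 253 with mice of both tissues alone, 324 with both exclusions and 17 to 152 without single arrays.

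The replicate number as a block gave 112 (79 higher, 33 lower) for CD33 ASO against CON ASO in cortex, 1021 and 415 (176 higher, 239 lower) for CON ASO against PBS in cortex and hippocampus, and changed no other count by over 1.5 times. That fit also left out arrays numbered above 9, so the block and the loss of arrays are not told apart. Without CON ASO replicate 12 alone and with no block, the 2 cortical counts were 58 and 586. Numbers were not taken as pairs, since correlations of deviations between same-numbered arrays ran from -0.445 to 0.525 over 124 pairs. Yet 26 arrays correlated best with their own number, where chance gives 10.8, and the medians over 12 comparisons ran from -0.107 to 0.223, against -0.0321 to 0.00954 for other numbers. Replicate numbers ran along the chips, so many same-numbered arrays shared a chip, and the chance value does not allow for this. A weak tie by number therefore cannot be told apart from a shared chip.

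With an estimated correlation the number of shifted lists went from 20 to 13 for genotype in cortex and from 20 to 9 in hippocampus, from 9 to 0 and from 6 to 2 for CD33 ASO against CON ASO, from 10 to 2 and from 17 to 1 for CON ASO against PBS, and from 6 to 1 and from 13 to 0 for CD33 ASO against PBS. With fry, which does not compare a list with other genes, the last 6 were 0, 2, 4, 10, 2 and 4. The cortical 9 became 17 both with mice of both tissues alone and without arrays of low weight, the hippocampal 6 became 13 with array weights, the cortical 10 became 16 with median centring, and the cortical 6 became 13 with median centring, 10 with no filter, with mice of both tissues alone and without arrays of low weight, and 12 with the striatum covariate. Lists whose test reversed direction were striatum under CON ASO, whose median shrank toward 0 without changing sign (-0.010), and choroid plexus under CD33 ASO against PBS (-0.0078), each with itself as covariate and so by construction, and hippocampal pan-microglia under CD33 ASO against CON ASO with both exclusions (0.051).

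Genes raised by the transgenes in cortex, at 0.024 under CD33 ASO, stood at 0.024 (p = 0.651) with an estimated correlation, at 0.019 without background correction (p = 0.0719), at -0.040 when chosen in the other tissue (p = 0.00179, 0.592 with an estimated correlation) and at -0.010 with mice of both tissues alone (p = 0.289, 0.812 estimated), both reversed. Those lowered stood at -0.040 (p = 0.129) with an estimated correlation, and at -0.09 when chosen in the other tissue (p = 2.19e-10, 0.115 estimated). In hippocampus those raised, at -0.024, reversed to 0.049 with both exclusions (p = 1.73e-04, 0.41 estimated) and to 0.017 without replicate 3 (p = 0.42, 0.861 estimated), and lost the call with an estimated correlation (-0.024, p = 0.5) and with mice of both tissues alone (-0.010, p = 0.153). Those lowered stood at 0.052 (p = 0.351) with an estimated correlation. The number of probes whose genotype effect differed between tissues, 503, was 967 with array weights, 239 with no mouse block and 300 with no filter. The 10 for CON ASO were 95 with array weights, 6 with chip as a block, and 0 with no mouse block or no filter. The 7 for CD33 ASO against PBS were 3 with array weights, 12 with mice of both tissues alone, and 0 with chip as a block, no mouse block, no background correction, no filter or without replicate 3. Limma gave 1586 and 1237 at an unadjusted p under 0.05.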

Other observations

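The tests of stress hormone and clock genes in this part were chosen only after the results were seen, and that of Avil against Cd33 before, with its reading of a relation that rests on few arrays set afterwards. In the oligodendrocyte and myelin list the largest fall under either oligonucleotide was Opalin, and other genes outside the lists moved with it in cortex: Tmem125 (-0.56 under CON ASO and -0.61 under CD33 ASO against PBS), the chloride channel gene Ano2 (-0.75 and -0.60) and the cyclin O gene Ccno (-0.64 and -0.67) were lower. In hippocampus the lipocalin gene Lcn2 rose by 1.01 under CON ASO (adjusted p = 0.0369, detected on 12 of 13 against 1 of 9 arrays), with the lysozyme gene Lyz2 at 1.10 (adjusted p = 2.13e-04). Creld2, a chaperone of the endoplasmic reticulum, rose under CON ASO in both tissues (0.22 and 0.28) and under CD33 ASO in hippocampus (0.33).

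Avil reading exposure to the CD33 oligonucleotide was a hypothesis written before the test, that mice with more Avil have less Cd33. Over 12 hippocampal CD33 ASO arrays Pearson r was -0.745 (permutation p = 0.00891, 0.0178 adjusted over both tissues) and Spearman rho -0.43 (permutation p = 0.17, adjusted 0.192). Without the pair of arrays farthest from the median, replicates 7 and 10, r was 0.082 (permutation p = 0.822), so the relation rests on them. Over 11 cortical arrays r was -0.356 (permutation p = 0.284) and rho -0.43 (permutation p = 0.192), and without the farthest pair r was -0.48 (permutation p = 0.196). No day holds enough of these mice for a value of its own, and whether Avil may follow exposure stays open. The Avil probe was not matched to the oligonucleotide's sequence, which was not used here.

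Hippocampal arrays labelled CD33 ASO replicates 7 and 10 lay at 0.13 and 0.0986 of the way from the PBS mean to the CON ASO mean over the 187 probes changed there, where PBS arrays ran from -0.22 to 0.24 and the other CD33 ASO arrays from 0.49 to 1.16. On the cortical scale APP/PS1 PBS arrays ran from -0.162 to 0.151, WT PBS arrays from 0.0565 to 0.471 and CD33 ASO arrays without replicate 3 from 0.275 to 1.17. Cortical CON ASO replicate 12 lay at 0.261, the others of its group at 0.74 to 1.29. The hippocampal array of the same mouse, CON ASO replicate 13, lay at 0.573, the others at 0.823 to 1.30. Of the CON ASO mice it had the lowest Fcna, Gpnmb, Lgals3 and Ms4a7 in each tissue.

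A glucocorticoid response may accompany oligonucleotide treatment. A list of 16 measured glucocorticoid target genes had a median of 0.181 under CON ASO in cortex (3 rose, adjusted p = 0.0146 with an estimated correlation) and 0.181 in hippocampus (3 rose, adjusted p = 0.0146). The chaperone gene Fkbp5 stood at 0.44 ± 0.09 in cortex (adjusted p = 0.0032) and at 0.22 ± 0.09 in hippocampus (adjusted p = 0.245). The hippocampal rises were Cdkn1a (0.72), Angptl4 (0.53) and Htra1 (0.26). Hif3a (-0.14), Per1 (-0.04) and Ddit4 (-0.03) lay lower, as did Klf9 (-0.06) and Mt2 (-0.01) in cortex, none called. Under CD33 ASO against PBS the median was 0.134 and 0.118 (adjusted p = 4.72e-04 and 0.0014 at the preset correlation, 0.112 and 0.119 estimated). Under CD33 ASO against CON ASO it was -0.063 and -0.078 (adjusted p = 0.0352 and 0.0014 at the preset correlation, 0.277 and 0.119 estimated). Whether a shift of the clock between groups plays a part stays open: 11 circadian clock genes had medians of 0.0434 and -0.0935 under CON ASO in cortex and hippocampus and of -0.0246 and -0.0305 under CD33 ASO, with 2 and 1 genes lower in cortex, and in the first the median and the test differed in sign. Collection times within a day were not used here.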
